A study of Mus musculus with 8 samples.

How the data were processed

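RNA was extracted from whole livers of 4 Myo5b knockout and 4 control neonatal CD1 mice with Trizol and a column kit, and sequenced by a commercial provider, per the labels' protocols. The deposited table holds whole-number read counts per Ensembl gene, which the authors made by aligning reads with Rsubread 2.20.0 in R 4.4.1 (with BiocManager 1.30.26), per the labels' protocols, and counting them with featureCounts, per the submitters' processing notes. The build is written there as GRMm38, read here as GRCm38. The annotation, strand setting, and treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as Cyp2a4, Sult2a8, the carboxylesterases and the globins, and genes overlapped by an antisense gene, are therefore uncertain, as are Gapdh and the mitochondrial transcripts, which have copies elsewhere in the genome and low counts for liver. The authors tested expression with DESeq2 1.46.0, per the series' design text; no fold change of theirs was used here.

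The table has 48440 genes, of which 35319 had at least 1 count and 48058 matched a gene symbol of GENCODE M21 (GRCm38), whose coordinates are printed. Library totals ran from 14228268 to 18398039 counts. The labels give each library its own animal, so each was counted as 1 sample, and no pair of libraries in a group was close enough to be 1 library entered again (chi-square per degree of freedom of 12.9 to 24.0). Groups came from the genotype in the labels, and no replicate number is shared between groups, so no pairing was made. The labels state ages only as a range for the series and give no batch, litter or sex for each pup, so none of these is a term of the main fit. Y-linked expression, which marks sex, entered an alternative fit as a covariate.

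Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr defaults (minimum count 10, minimum total count 15), which left 18274. Libraries were scaled by TMM, and genotype was tested by the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values are scaled by TMM library sizes, and log2 CPM use a prior count of 2. Gene lists were tested with camera, with an inter-gene correlation preset at 0.01 and, as an alternative, estimated, over the 37 lists with at least 5 tested genes. Camera compares a list's genes with all other genes. The alternative fry asks a different question, whether a list's genes change in a common direction, without comparing them with other genes. Single values were compared by exact two-sided permutation tests over all 70 assignments. Principal components used centred log2 CPM of the 500 most variable genes. Figures were drawn with matplotlib 3.10.9.

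The gene lists, the design, the alternatives and the naming rule were set before the data were examined. The rule names Myo5b; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM, knockout values all on 1 side of the controls, and a gene symbol that is not a clone or predicted name; the 3 genes with the smallest p in each of 8 primary lists and 1 in each other list of cell types and pathways; and Mki67, Glul, Cyp2e1, Cyp7a1, Cyp8b1, Abcb11, Slc10a1 and Afp. Genes named beyond it, such as the periportal genes that rose and the transporter Abcc2, were chosen after their values were seen. A sex-linked list was left out of the set test. In 3 simulated runs of the knockout against control comparison over 17874 genes, with 200 genes changed per run, the test recovered 31.6% of genes changed 1.5-fold, 61.8% of those changed 2-fold and 90.4% of those changed 4-fold, with 6.37% false calls among calls. Those runs changed a far smaller share of genes than the 20.7% called in the data, which makes the Benjamini-Hochberg cut-off stricter. The recoveries can therefore understate those of the real comparison, though modest changes can still be missed. In the same runs all 3 shifted lists and 0 of 90 unshifted lists were called. Those lists held random genes drawn independently of each other, so they do not test the preset correlation for real lists. The estimated correlation was 0.86 for the erythroid list, and balanced splits of the real libraries gave 0 to 9 called lists.

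The alternatives were median-ratio and upper-quartile scaling and library size alone; no low-count filter and a filter of at least 1 CPM in 4 libraries; non-robust dispersion; DESeq2 1.42.0; limma-voom with quality weights; a minimum fold of 1.5; covariates for erythroid markers and for Y-linked genes; leaving out the 10 genes above 1% of counts in any library; the fry set test; other gene choices and scalings for principal components; and each library left out in turn. The periportal minus pericentral difference and the joint omission of knockout 278 and control 282 were added after the data were seen, as was the erythroid covariate with an estimated correlation or with fry.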

Results

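Gene expression was measured by RNA sequencing of whole liver from 8 neonatal CD1 mice. The livers came from 4 pups with a germline deletion of Myo5b and from 4 control littermates that were heterozygous or wildtype. Myo5b encodes myosin Vb, an actin motor that carries recycling endosomes towards the apical membrane, which in hepatocytes is the wall of the bile canaliculus. Pups were killed at 3 to 8 days of age, and the labels give neither the age, the sex nor the litter of each pup, so none is a term of the main comparison. The knockout livers (animals 275, 276, 277 and 278) had 17185634, 15134291, 18398039 and 16166508 counts, and the control livers (animals 279, 280, 281 and 282) had 15967851, 15872148, 17007771 and 14228268. Each library is a separate animal.

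The comparison asks how loss of myosin Vb changes the neonatal liver, with proliferation, zonation and bile acid genes as the themes named in the series title. Myo5b itself (chromosome 18, 74440936 to 74771493 on GRCm38, GENCODE M21) was 2.69-fold lower in the knockout livers, at 49.3 ± 7.06 CPM (counts scaled to a common library total; SD, n = 4) against 133 ± 33.1 CPM in controls. Its log2 fold change was -1.43 (SE 0.18), with an adjusted p of 3.14e-04 in edgeR's quasi-likelihood test. The 4 knockout values (43.1 to 59.5 CPM) all lay below the 4 control values (94.0 to 172 CPM). With erythroid marker expression as a covariate, Myo5b was -1.001 (SE 0.56) and not called. Counts cover the whole gene, and the exons that the allele lacks are not given in the sources used here, so the remaining counts do not measure intact transcript.

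Knockout and control livers differed widely. Of 18274 genes tested, 1694 were higher and 2088 lower in knockout livers at an adjusted p under 0.05, and 410 and 672 of these changed more than 2-fold. The called genes were 20.7% of those tested, and counts of called genes in single lists are to be read beside that share. Genotypes separated on the first principal component of the 500 most variable genes, which held 49.7% of the variance (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows). The 4 knockout livers scored 13.3 to 27.2 and the 4 control livers -26.7 to -15.5. With library size as the only scaling, 2300 genes were higher and 1696 lower, which moved the share of higher calls from 44.8% to 57.6%. With a minimum fold of 1.5 in the test, 217 were higher and 500 lower. Erythroid marker genes were lower in every knockout liver, and with their mean expression as a covariate 18 genes were higher and 16 lower. Of the 65 called genes that the naming rule gave, 61 lost their call (Cyp4f14, Uroc1, Akr1d1 and Igfbp1 kept it). Genes named beyond the rule were not counted. Of those 61 genes, 57 kept their direction. Among these, 14 had a log2 fold change at least as large and 16 had one more than 2 times smaller. The median ratio to the fold without the covariate was 0.687, while the median SE went from 0.14 to 0.42. The loss of calls therefore reflects wider errors as well as smaller folds. Across the 8 libraries that covariate correlated with genotype at -0.95, and it inflated the variance of the genotype term 9.50-fold.

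**Figure D1:**
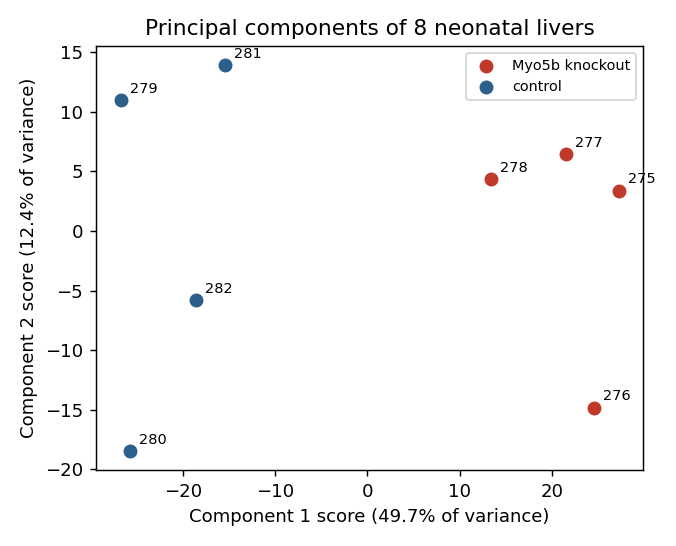
Scores of the 8 livers on the first (x axis) and second (y axis) principal components of log2 CPM of the 500 most variable genes, with animal numbers beside the points. Knockout livers (red) lie at 13.3 or above on component 1 and control livers (blue) at -15.5 or below.

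The largest rise among genes that met the naming rule was that of Apoa4, an apolipoprotein of triglyceride-rich particles, at 894 ± 388 CPM in knockout livers against 37.0 ± 15.9 CPM in controls (SD, n = 4; log2 fold change 4.59, SE 0.53). Ubd, a ubiquitin-like protein induced by inflammatory cytokines, followed with 4.13 (SE 0.58), then Cyp2a4 with 3.62 (SE 0.70), the leptin receptor gene Lepr with 3.49 (SE 0.37), Cntnap1 with 3.43 (SE 0.24) and Zan with 3.36 (SE 0.50). Slc22a7, an organic anion transporter, fell furthest, from 18.8 ± 7.07 CPM to 0.447 ± 0.518 CPM (log2 fold change -5.43, SE 0.74). Clec2h (-4.69), Cyp4f14 (-4.46), Car5a (-4.36), the water channel Aqp8 (-3.99) and Cyp2f2 (-3.95) were the next falls. The adjusted p of these 12 genes ranged from 2.79e-09 to 0.0192. Aqp8 lost its call when knockout 276 (log2 fold change -3.77), knockout 277 (-3.84), control 279 (-3.95) or control 280 (-3.91) was left out. Cyp2a4 has a near-identical neighbour, Cyp2a5, so its value is uncertain. With the erythroid covariate Cyp2a4 turned to -1.25 (SE 0.72). Among these 12 genes only Cyp4f14 (-4.70) kept its call in that fit, and Clec2h (-0.35), Aqp8 (-0.37) and Zan (0.38) came nearest 0.

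**Figure D2:**
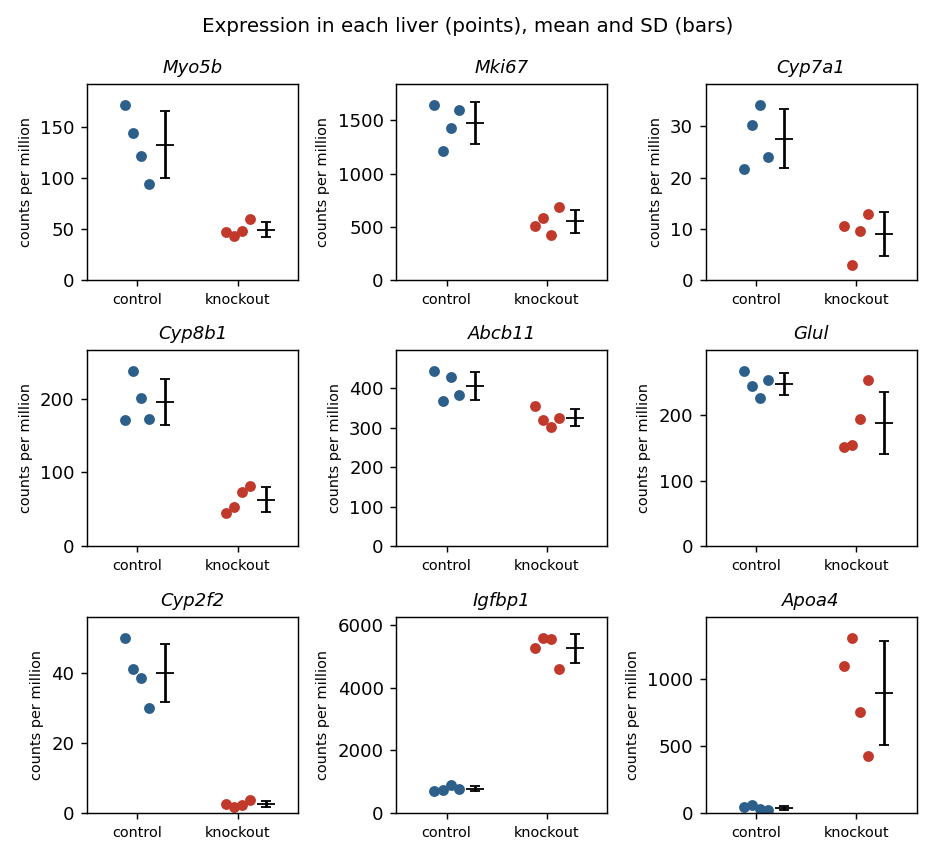
Expression of 9 genes in each liver, in CPM on a linear axis from 0, with control livers in blue and knockout livers in red; bars give the mean and SD of 4 livers. Myo5b, Mki67, Cyp7a1, Cyp8b1, Abcb11 and Cyp2f2 were lower and Igfbp1 and Apoa4 higher in all 4 knockout livers than in any control, while Glul overlapped.

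Cell-cycle genes were lower in the knockout livers. All 25 genes of S phase and DNA replication and all 25 of G2 and mitosis fell, with median log2 fold changes of -1.09 and -1.16. The counts adjusted over the list alone were the same, which follows from every member passing over all genes and adds no evidence. Rrm2, a subunit of ribonucleotide reductase, fell from 112 ± 12.7 to 29.6 ± 4.37 CPM (log2 fold change -1.91, SE 0.11, adjusted p = 2.98e-08). The replicative helicase subunits Mcm6 and Mcm2 had log2 fold changes of -1.24 (SE 0.10) and -1.19 (SE 0.09). Among mitotic genes, Birc5 (-1.65, SE 0.14), Ube2c (-1.44, SE 0.14) and Prc1 (-1.16, SE 0.11) fell. Mki67, the gene of the proliferation antigen Ki-67, fell from 1474 ± 196 to 550 ± 109 CPM (log2 fold change -1.42, SE 0.14, adjusted p = 1.19e-05). In camera with a preset correlation, the adjusted p was 8.22e-41 for S phase and 1.67e-41 for G2 and mitosis. For S phase the adjusted p was 0.0393 with an estimated correlation, and for G2 and mitosis adjusted p = 0.0525 with an estimated correlation. Erythroid markers fell in the same livers, with a median of -1.89.

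Periportal hepatocyte genes were mostly lower, while pericentral genes moved in both directions. Of 23 periportal genes, 13 fell and 5 rose (16 fell and 5 rose adjusted over the list alone), with a median log2 fold change of -0.65. Cyp2f2 fell from 40.0 ± 8.36 to 2.59 ± 0.834 CPM, and the urea-cycle gene Otc (log2 fold change -1.21, SE 0.10) and Uroc1, of histidine breakdown (-1.15, SE 0.10), fell too. Ctsc, Pigr, Slc7a2 and Rnase4 rose, as did Hsd17b6 (0.46), a call lost without knockout 275 (0.42), 276 (0.38) or 277 (0.48) and without control 279 (0.51), 281 (0.47) or 282 (0.33). Of 25 pericentral genes, 4 rose and 6 fell (5 and 7 adjusted over the list alone), with a median of -0.03. Those that rose were 2 without knockout 275 or 276 or control 279, 281 or 282, and those that fell were 3 without knockout 276. Axin2, a Wnt target, rose by 0.78 (SE 0.12), while Rgn (-0.87, SE 0.09) and Lect2 (-0.98, SE 0.12) fell. The classical pericentral genes Glul (log2 fold change -0.40, SE 0.15, adjusted p = 0.0825) and Cyp2e1 (-0.33, SE 0.17, adjusted p = 0.205) did not pass the test. Both passed it without knockout 278, at -0.57 and -0.56, in limma-voom (-0.47 and -0.41) and with no low-count filter (-0.40 and -0.33), as Glul did in DESeq2 (-0.39), and Cyp2e1 was 1306 CPM in that liver against 741 to 803 CPM in the other knockouts.

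The periportal list was called by camera (adjusted p = 7.81e-08) and the pericentral list was not (adjusted p = 0.731). The periportal call did not hold with an estimated correlation (adjusted p = 0.305 with an estimated correlation). The mean log2 CPM of periportal genes minus that of pericentral genes was 1.61 ± 0.07 in knockout and 2.20 ± 0.25 in control livers (SD, n = 4), a difference of -0.60 (exact permutation p = 0.0286, two-sided). This difference was chosen after the data were seen, and it missed the threshold when any of the knockouts 275, 276, 277 or 278 was left out, at -0.62, -0.59, -0.61 and -0.57. Control 282 (1.83) lay between the knockouts (1.52 to 1.68) and the other controls (2.33). Every knockout thus lay below every control, whichever knockout was left out. Erythroid markers and hepatocyte maturation genes fell in the same livers.

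**Figure D3:**
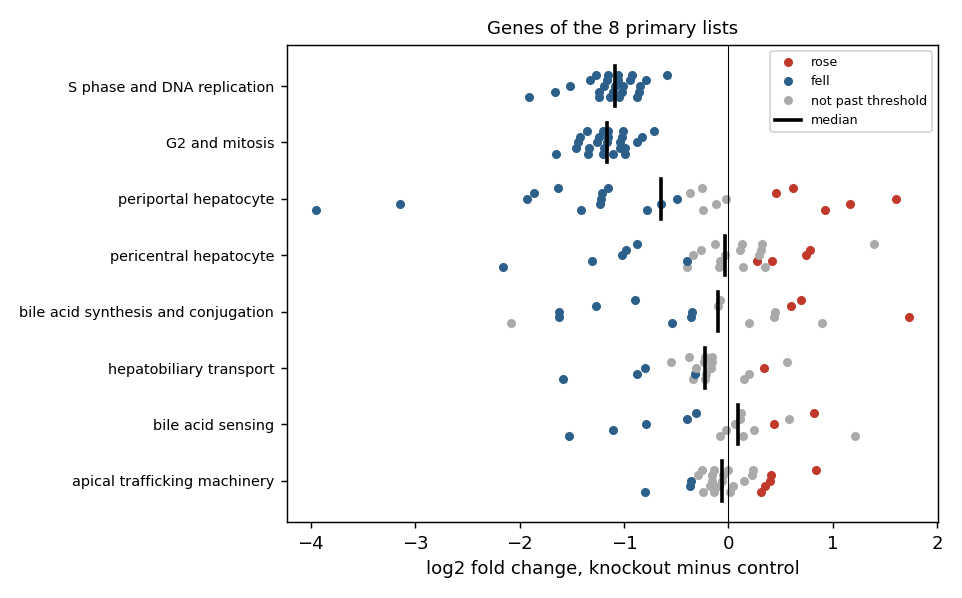
Log2 fold changes (knockout minus control) of single genes in 8 gene lists, with red for genes that rose, blue for those that fell, grey for those not past an adjusted p of 0.05, and a black bar for the median. Both cell-cycle lists lie wholly below 0 (medians -1.09 and -1.16), and the other lists hold genes on both sides of 0.

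Single bile acid genes changed in both directions, and camera called none of the 3 bile acid lists. Of 17 genes of bile acid synthesis and conjugation, 7 fell and 3 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.09. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell from 195 ± 31.0 to 63.3 ± 17.4 CPM (-1.63, SE 0.21, adjusted p = 7.93e-04). Cyp7a1, the rate-limiting enzyme of the classical pathway, fell from 27.6 ± 5.75 to 8.93 ± 4.29 CPM (-1.62, SE 0.40, adjusted p = 0.0271). The Cyp7a1 call was lost when knockout 275 (-1.70), knockout 277 (-1.66), control 280 (-1.58) or control 281 (-1.50) was left out, with no low-count filter (-1.62), and with Y-linked expression as a covariate (-1.60). Akr1d1 fell by 1.27 (SE 0.10), whereas Cyp39a1, an oxysterol hydroxylase, rose by 1.73 (SE 0.20) and Slc27a2 by 0.70 (SE 0.09). Camera did not call the list (adjusted p = 0.416).

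Of 19 hepatobiliary transport genes, 4 fell and 1 rose, likewise adjusted over the list alone. The bile salt export pump gene Abcb11 fell from 405 ± 35.5 to 325 ± 21.6 CPM (-0.32, SE 0.09, adjusted p = 0.0140), a call lost without control 279 (-0.27). Slco1a4 fell by 1.58 (SE 0.32), and the sterol transporter genes Abcg5 (-0.88, SE 0.19) and Abcg8 (-0.80, SE 0.17) fell. The canalicular transporter gene Abcc2 (0.34) rose, a call lost without knockout 275 (0.27) or control 279 (0.30), and without knockout 278 the number that fell was 7. Slc10a1, the bile acid uptake transporter, was 175 ± 14.9 against 195 ± 21.9 CPM (-0.15, SE 0.09, adjusted p = 0.268). Camera did not call this list (adjusted p = 0.112), but did when knockout 277 (adjusted p = 0.0498) or control 282 (0.0489) was left out and with no low-count filter (0.0336). The fry test, which does not compare a list with other genes, called it (0.0187), as it did 17 of the 37 lists. Of 16 bile acid sensing genes, 5 fell and 2 rose (the same adjusted over the list alone). The number that rose was 4 without knockout 278 and 1 without any other single library, and the number that fell was 3 without knockout 276 or control 280. Sult2a8 (-1.53, SE 0.21) and Fgfr4, the receptor for FGF15 (-0.79, SE 0.11), fell, while Osgin1 rose by 0.82 (SE 0.13). The list's median was 0.09, its mean -0.03, and camera's direction was down (adjusted p = 0.665). Fry called the list lower (0.0203), which does not say that it fell further than other genes. Sult2a8 belongs to a family of near-identical genes and is uncertain.

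Of 25 genes of the apical trafficking machinery that myosin Vb works with, 5 rose and 3 fell, also adjusted over the list alone, and 3 rose without knockout 275 or 277 or control 280. Over all genes tested 20.7% were called, so these counts alone do not set the list apart. Pard3, a polarity protein, rose by 0.40 (SE 0.07), and Stxbp2, which regulates vesicle fusion, rose by 0.41 (SE 0.10). Myo5c, a related myosin V motor, fell by 0.79 (SE 0.19). The list was not called (adjusted p = 0.976), and its median (-0.06) and mean (-0.01) had the opposite sign to camera's direction.

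Of 22 postnatal hepatocyte maturation genes, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.69, and 1 rose without knockout 275 or control 280, 281 or 282. Cyp4f14 fell from 24.1 ± 1.05 to 1.09 ± 0.417 CPM. The list was called (camera adjusted p = 2.12e-17), and the adjusted p was 0.0173 with an estimated correlation. Erythroid markers fell in the same livers (median -1.89). Of 14 genes of the insulin-like growth factor axis, 4 fell and 3 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.112, but 0.0220 without control 282 and 0.0195 in fry). Igfbp1, which encodes a binding protein induced in fasting, rose from 774 ± 87.8 to 5268 ± 463 CPM (2.77, SE 0.10, adjusted p = 7.01e-11). Igf1, Igfals and Ghr were among those that fell, at -2.62 (SE 0.18), -2.50 (SE 0.16) and -1.26 (SE 0.11). These 3 genes were picked after their values were seen. Of 21 genes of secreted hepatocyte proteins, 6 fell and 2 rose (7 and 2 adjusted over the list alone). Transthyretin (Ttr) fell by 0.97 (SE 0.10). This list was called (adjusted p = 0.0419), with a median of -0.01, and adjusted p = 0.866 with an estimated correlation. Its call was also lost without knockout 276 (0.0953) or 277 (0.0591) or control 280 (0.138), with upper-quartile scaling (0.0581), with library size alone (0.0740) and with a filter of at least 1 CPM in 4 libraries (0.0555). Of 19 fetal liver genes, 6 fell and 5 rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.106), and 3 rose without knockout 276 or control 279 or 282. This list was called lower without knockout 277 (0.0478) or control 281 (0.0418), with no low-count filter (0.0269) and with Y-linked expression as a covariate (0.0370) and in fry (0.00992). Dlk1 fell by 1.22 (SE 0.14), and Afp was 9686 ± 2642 against 13008 ± 1522 CPM (-0.43, SE 0.19, adjusted p = 0.154), and passed in DESeq2 (-0.42).

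Of 26 genes of fatty acid oxidation and ketogenesis, 12 rose and 3 fell (15 and 4 adjusted over the list alone), with a median of 0.39. The number that rose was 7 without control 279, and the number that fell was 0 without knockout 275 and 1 without knockout 278 or control 279, 280 or 282. Vnn1, a target of the fatty acid receptor PPAR-alpha, rose from 26.0 ± 2.96 to 77.1 ± 12.4 CPM (1.57, SE 0.13). The list was called (camera adjusted p = 6.18e-05), but adjusted p = 0.651 with an estimated correlation. Erythroid markers fell in the same livers, and with their expression as a covariate the list turned in direction and lost its call (adjusted p = 0.0556). Its mean log2 CPM was 7.31 in both knockout 278, the knockout with the highest erythroid score, and control 280. Of 15 oxidative stress response genes, 6 fell and 1 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.00546; adjusted p = 0.348 with an estimated correlation). Without knockout 278, 2 of these rose. Ces2g fell by 2.16 (SE 0.15), though it is one of several closely related carboxylesterase genes. Of 16 immediate early genes, 5 rose and none fell (6 adjusted over the list alone; 1 fell without control 282; camera adjusted p = 0.00571; adjusted p = 0.305 with an estimated correlation). Klf6 rose by 0.60 (SE 0.12).

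Markers of several cell types differed between the genotypes. All 25 erythroid genes fell, with a median of -1.89, and Xpo7 fell by 1.35 (SE 0.11). That all fell too when adjusted over the list alone follows from this and adds no evidence. Globin genes took 0.235% ± 0.080 of counts in knockout livers and 0.752% ± 0.104 in controls (SD, n = 4; exact permutation p = 0.0286, two-sided). Of 13 megakaryocyte and platelet genes, 4 fell, likewise adjusted over the list alone (2 without knockout 276 or control 279 or 282), and Ppbp fell by 0.94 (SE 0.21). Of 15 Kupffer cell and macrophage genes, 12 rose, likewise adjusted over the list alone, with a median of 0.71, and Mpeg1 rose by 1.17 (SE 0.10). Of 20 genes of sinusoidal and vascular endothelium, 14 rose (19 adjusted over the list alone), with a median of 0.44, and Bmp2 rose by 1.37 (SE 0.11). Of 25 interferon response genes, 14 rose and none fell (17 adjusted over the list alone), with a median of 1.14, and Usp18 rose by 1.20 (SE 0.16). The mean log2 CPM of the interferon list was 4.08 in control 281, against 3.02 to 3.35 in the other controls and 4.31 to 4.85 in knockouts, and without control 281 the number that rose was 21. Camera called the erythroid (adjusted p = 5.48e-38), megakaryocyte (0.0169), Kupffer cell (1.76e-14), endothelial (8.91e-10) and interferon (9.92e-11) lists. The megakaryocyte call was lost without control 279 (0.0516) or 282 (0.0532), without knockout 278 and control 282 (0.0607) and in fry (0.0862). With an estimated correlation all 5 calls were lost, at adjusted p = 0.123, 0.699, 0.0525, 0.209 and 0.238 with an estimated correlation.

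**Figure D4:**
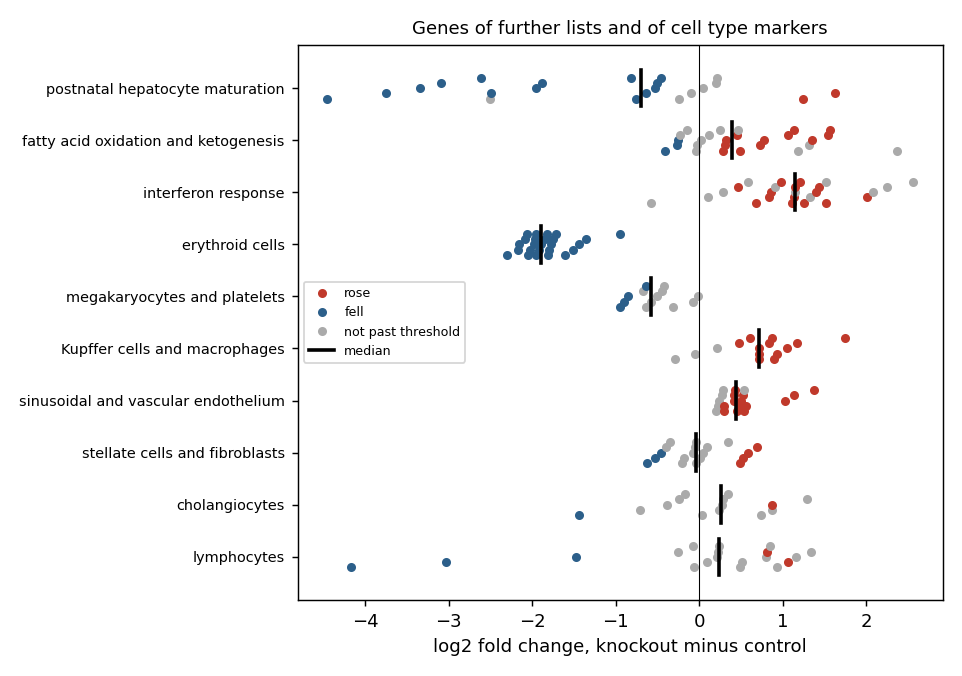
Log2 fold changes (knockout minus control) of single genes in 10 further lists, drawn as for the bile acid and zonation lists. The erythroid list lies wholly below 0 (median -1.89), and the Kupffer cell, endothelial and interferon lists lie mostly above 0 (medians 0.71, 0.44 and 1.14).

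Stellate cell and fibroblast genes (19 tested, 4 rose and 3 fell; 4 and 4 adjusted over the list alone), cholangiocyte genes (14, 1 rose and 1 fell; the same adjusted over the list alone) and lymphocyte genes (19, 2 rose and 3 fell; the same adjusted over the list alone) had no common direction. Without single libraries, 1 stellate cell gene fell (knockout 275 or control 280 left out), 2 cholangiocyte genes rose (knockout 278 or control 280) and 1 lymphocyte gene rose (knockout 275, 276 or 278 or control 279, 280 or 281). Their camera adjusted p were 0.942, 0.731 and 0.665. Dcn rose by 0.58 (SE 0.12) and Krt23, a keratin, by 0.87 (SE 0.17), while Igll1, a gene of B cell precursors, fell from 1.73 ± 0.716 to 0.0902 ± 0.121 CPM. Of 17 neutrophil genes, 3 fell, likewise adjusted over the list alone (adjusted p = 0.626; 1 rose without knockout 277), among them Mmp8 (-1.21, SE 0.25). Of 7 genes of neighbouring tissues, 1 rose, likewise adjusted over the list alone (adjusted p = 0.942): Vil1, at 1.38 (SE 0.42), a call lost without knockout 275 (1.28), knockout 277 (1.26), control 280 (1.16) or control 282 (1.13). Of 12 mitochondrial transcripts, 11 fell, likewise adjusted over the list alone, with a median of -1.06 (camera adjusted p = 8.91e-18; adjusted p = 0.0843 with an estimated correlation). The mitochondrial chromosome took 0.234% ± 0.034 of counts in knockout livers and 0.420% ± 0.016 in controls (exact permutation p = 0.0286, two-sided; SD, n = 4). These shares are low for liver, and reads that also match nuclear copies may have been lost, so the values are uncertain.

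The remaining lists were not called. Cholesterol synthesis (24 tested, 4 rose and 5 fell; 5 and 5 adjusted over the list alone) had a camera adjusted p of 0.942, and Ebp fell by 0.59 (SE 0.10). Fatty acid synthesis (18, 5 rose and 6 fell; 8 and 6 adjusted over the list alone) had 0.584, and Srebf1, a lipogenic transcription factor, fell by 0.77 (SE 0.09). Gluconeogenesis (14, 2 rose and 3 fell; 2 and 4 adjusted over the list alone) had 0.665, and Igfbp1, also in this list, had its smallest p. Glucocorticoid response (13, 3 rose and 1 fell; the same adjusted over the list alone) had 0.584, and Zbtb16 rose by 1.37 (SE 0.15). The p53 targets (14, 1 rose and 2 fell; the same adjusted over the list alone) had 0.785, and Gtse1, itself a cell-cycle gene, fell by 1.55 (SE 0.24). The amino acid and integrated stress response (17, 1 rose and 2 fell; the same adjusted over the list alone) had 0.942, and Shmt2 fell by 0.99 (SE 0.11). Endoplasmic reticulum protein folding (16, 2 rose and 1 fell; 3 and 2 adjusted over the list alone) had 0.665, and Dnajc3 rose by 0.51 (SE 0.09). The acute phase response (24, 8 rose and 4 fell; the same adjusted over the list alone) had 0.584, and Cp rose by 0.48 (SE 0.09). The hypoxia response (19, 3 rose and 5 fell; 4 and 5 adjusted over the list alone) had 0.606, and Pdk1 fell by 0.71 (SE 0.11). Circadian clock genes (15, 1 fell, also adjusted over the list alone) had 0.785, and Hlf fell by 0.62 (SE 0.14). Nuclear retained transcripts (6, 1 rose and 2 fell; the same adjusted over the list alone) had 0.976; Malat1 rose and Meg3 and Mirg fell, named after their values were seen. Mirg (-0.60) lost its call without knockout 275 (-0.54), 276 (-0.52) or 277 (-0.66) or control 279 (-0.57), 280 (-0.66) or 281 (-0.40). The median, mean and test did not share a sign for cholesterol synthesis, fatty acid synthesis, gluconeogenesis, nuclear retained transcripts, neutrophils, lymphocytes, stellate cells and neighbouring tissues. Several of these counts moved by over 1.5 times when 1 library was left out. For cholesterol synthesis 2 rose without knockout 276 or 277 or control 279, 281 or 282, and 3 fell without knockout 275 or control 280. For fatty acid synthesis 3 fell without knockout 275 or 276 or control 279 or 280, and for the hypoxia response 3 fell without knockout 275 or control 280 or 281 and 2 without knockout 276. Among p53 targets 1 fell without knockout 276 or 277 or control 279 or 282, and in the acute phase response 2 fell without control 280. For glucocorticoid response 3 fell without knockout 278, and for the amino acid and integrated stress response 2 rose without knockout 278 or control 282. In endoplasmic reticulum protein folding 1 rose without control 281 and 2 fell without knockout 277. Among clock genes 1 rose without knockout 276 or 278, and 2 fell without knockout 277 or 278 or control 279 or 282.

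In all, camera called 14 of 37 lists, 9 lower and 5 higher, and 2 with an estimated correlation (S phase and hepatocyte maturation). With erythroid expression as a covariate it called 17, among them S phase (adjusted p = 1.57e-07), G2 and mitosis (1.51e-05) and periportal genes (6.41e-13), all lower. That fit ended the erythroid call (0.995), as it must, since the covariate is the mean of that list. It also ended the calls of fatty acid oxidation (0.0556), immediate early (0.392), megakaryocyte (0.0570) and endothelial genes (0.0570), with fatty acid oxidation and megakaryocyte genes turned in direction. It called bile acid synthesis (0.00953), endoplasmic reticulum protein folding (0.00181), the insulin-like growth factor axis (0.0235), fetal liver (0.0457) and stellate cell genes (0.00515) lower, and the integrated stress response (3.23e-04), neutrophil (0.00327) and lymphocyte genes (0.00307) higher. With that covariate and an estimated correlation 0 lists were called, and 5 had an unadjusted p under 0.05. Other splits of the same 8 libraries into 4 and 4 gave 9 to 17 called lists with the preset correlation where 3 knockouts lay on 1 side, which keeps part of the genotype difference, and 0 to 9 where the genotypes were balanced.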

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

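The tests of erythroid cells, of scaling, of pup age, of cell type markers and of single libraries were chosen only after the results they concern were seen, as was that of genes of like GC content and length, whereas the splits of the libraries and the removal of the GC and length trend were not. Across 156 groups of 4 values, 14 had a library far from the other 3 (by the gap to its nearest neighbour over the range), where chance gives about 1 group in 20.

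Control 282 stood apart for 6 values. It had 41.4 CPM of Abcg5 (others from 52.2 CPM), 107 CPM of Sult2a8 (others up to 94.4 CPM), 154 CPM of Srebf1 (others from 190.5 CPM), 47.7 CPM of Hlf (others up to 38.2 CPM) and 20.3 CPM of Klf6 (others from 25.5 CPM). Its ribosomal RNA genes took 0.191% of counts, against 0.0566% to 0.0707% in the other controls. Knockout 278 stood apart for 4 values: Axin2 at 41.3 CPM, Vnn1 at 58.6 CPM, Krt23 at 48.7 CPM and Cyp2e1 at 1306 CPM. The others were control 281, with Ubd at 2.97 CPM, Mpeg1 at 94.9 CPM and 0.444% of counts from the mitochondrial chromosome, and control 279, with Vnn1 at 21.6 CPM. Without knockout 278 and control 282, 1589 genes were higher and 2052 lower.

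Chance is argued against for the counts of genes only as far as 35 splits of the 8 libraries into 4 and 4 allow. Of these, 1 (the real one) gave as many genes in a direction, with 1694 higher and 2088 lower. Any other split gave at most 1 gene. Every other split mixes the genotypes, which widens the spread within its groups and lowers its calls. The size of that gap is therefore no measure of chance. By the same count chance is not argued against for the number of called lists. There, 4 of the 35 splits, the real one included, gave at least the real 14, and the highest other gave 17. The other 3 had 3 knockouts on 1 side and so kept part of the genotype difference, and the 18 balanced splits gave 0 to 9.

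The lower cell-cycle lists moved with the erythroid list, and erythroid precursors divide in the neonatal liver. Bias by GC content and transcript length is argued against by the 100 genes nearest each cell-cycle gene in both, whose median was 0.024 (the trend across genes was too flat, at Spearman 0.017 and 0.054, for its removal, which left -1.15, to be a test), and scaling by medians of -1.07 with library size alone and -1.15 without abundant genes. Fewer erythroid cells could account for some or all of the fall: they would need to hold 0.748 of control cell-cycle transcripts, and within groups both scores rose together (r = 0.87, permutation p = 0.0243; rho = 0.80, permutation p = 0.0625; 8 libraries, 576 assignments), which rests largely on knockouts 277 and 278 (r = 0.55 without them). With the erythroid covariate the median moved from -1.14 to -0.55 (median SE 0.36), Rrm2 to -1.33 and Mki67 to -0.29, and both lists stayed called lower with the preset correlation (adjusted p = 1.57e-07 and 1.51e-05) but not with an estimated one (0.272 and 0.316). Because that covariate nearly follows genotype, this fit does not decide whether erythroid loss is the whole cause, and lower division of hepatocytes stays open as a hypothesis.

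Of hepatocyte maturation genes 14 of 22 fell and 2 rose, and all 25 erythroid genes fell, though liver erythropoiesis wanes while hepatocytes mature after birth. A younger age of the knockout pups as the whole cause would leave erythroid genes higher, but their median was -1.89. An older age as the whole cause would leave maturation genes higher, but their median was -0.69. An effect of the germline deletion, whether direct on the liver or indirect, and age differences combined with it, stay open. The labels do not give the age of each pup.

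Beside the erythroid fall, 12 of 15 Kupffer cell, 14 of 20 endothelial and 14 of 25 interferon genes rose and none fell, though no list stayed called with an estimated correlation (adjusted p = 0.0525, 0.209 and 0.238). A lower erythroid share that raises every other cell type alike is argued against by the 7 other lists of liver and blood cell types, which moved apart. Mean log2 CPM of Kupffer cell genes was 6.15 ± 0.11 in knockouts against 5.44 ± 0.12 in controls (SD, n = 4). For stellate cell genes it was 5.56 ± 0.12 against 5.57 ± 0.13. Medians ran from -0.58 for megakaryocyte to 0.71 for Kupffer cell genes. Their Kruskal-Wallis H was 44.1 (permutation p = 1.00e-04 across genes, which are not independent replicates). It was computed after the calls of these lists were seen, so it adds no separate evidence. The excess of 0.43 of Kupffer cell and endothelial genes over stellate, cholangiocyte and lymphocyte genes is no test, since those lists were grouped by their calls. A single deviant library is argued against too, since 35 to 44 of these genes passed whichever library was left out, against 40 with all 8. More such cells, more transcript per cell, and a response to the genotype stay open as hypotheses.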

How the results depend on the processing

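The periportal minus pericentral difference and the joint omission of knockout 278 and control 282 were chosen after the data were seen, as was the erythroid covariate with an estimated correlation or fry. Across the other scalings, filters, dispersions and tools, genes higher ranged from 1641 to 2300 and genes lower from 1696 to 2290, and Myo5b kept its call, from -1.36 to -1.44. Leaving out each library gave 1223 to 1762 higher and 1699 to 2167 lower, with Myo5b from -1.28 to -1.56, and the genotypes stayed apart on component 1. A minimum fold of 1.5 gave 217 higher and 500 lower.

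With erythroid expression as a covariate, which nearly follows genotype (variance inflated 9.50-fold), 18 genes were higher and 16 lower and Myo5b was -1.001 without a call. Of the 65 called genes that the naming rule gave, 61 lost their call, of which 57 kept their direction. Among these, 14 had a fold at least as large and 16 one more than 2 times smaller. The median ratio was 0.687, while the median SE went from 0.14 to 0.42. In all, 6 named genes turned: Cyp2a4 to -1.25, Slco1a4 to 0.13, Ppbp to 0.26, Dcn to -0.26, Glul to 0.48 and Cyp2e1 to 0.65. Elsewhere 2 named genes gained a call in DESeq2, 2 in limma-voom and 2 without a filter, and 1 lost it without a filter and 1 with a Y-linked covariate, which gave 1482 higher and 1898 lower. The pericentral list turned with the erythroid covariate (adjusted p = 0.982) and the bile acid synthesis list was called (0.00953), while 17 lists were called and S phase (1.57e-07), G2 and mitosis (1.51e-05) and periportal genes (6.41e-13) stayed called lower. With an estimated correlation besides, 0 lists were called (5 at an unadjusted p under 0.05), with S phase at 0.272, G2 and mitosis at 0.316, periportal at 0.272 and pericentral, turned, at 0.982. With fry besides, 0 were called (6 unadjusted), at 0.110, 0.264, 0.151 and, turned, 0.924.

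An estimated correlation left 2 lists, with G2 and mitosis at 0.0525 and periportal at 0.305. Fry called transport (0.0187) and bile acid sensing (0.0203), and the trafficking list turned (0.740). Trafficking also turned without control 282 (0.993) and without knockout 278 and control 282 (0.988). Without a filter transport was called (0.0336). For leave-one-out, transport ranged from 0.0489 to 0.210 and trafficking from 0.831 to 0.993. The periportal minus pericentral difference ranged from -0.72 to -0.56, lost its call without any 1 knockout, and was -0.69 without knockout 278 and control 282, where 3 against 3 cannot reach 0.05. The cause of these changes was not tested, apart from that limit of 3 against 3 and the call lost without any 1 knockout. With 1 library left out a p under 0.05 can still be reached, so that limit does not account for this lost call. The knockouts left (1.52 to 1.68) still lay below every control. Control 282 (1.83) lay nearer to them than to the other controls (2.33). Setting those other controls against control 282 and the knockouts left therefore gave a wider difference than genotype did, and the two-sided test missed the threshold.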

Other observations

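The gene lists in this part, and the test of macrophages below, were chosen after the data were seen, so their counts describe these livers, are not independent evidence, and come with no set test. All 10 genes of MHC class II presentation rose, with a median log2 fold change of 1.71, and the invariant chain gene Cd74 went from 39.1 to 234 CPM (2.58, SE 0.14, adjusted p = 2.68e-07 in edgeR). Of 11 genes of MHC class I presentation, 9 rose (11 adjusted over the list alone), with a median of 1.37, H2-D1 by 1.41 (SE 0.12). The number that rose was 6 without knockout 275 or 276 or control 279 or 280, and 11 without control 281. Of 12 interferon gamma inducible GTPase genes, 3 rose (Tgtp2, Gbp5 and Gbp7; 8 adjusted over the list alone) with a median of 1.78. That count was unstable: it was 0 without control 280, 11 without control 281 and 1 without any other one. Tgtp2 and Gbp7 lay near the threshold (adjusted p = 0.0425 and 0.0468 in edgeR). Control 281 had the highest mean of the interferon list among controls (4.08 log2 CPM). Tgtp2 has a near-identical copy.

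Of 12 carboxylesterase genes, 10 fell (11 adjusted over the list alone), with a median of -1.17, Ces1g (-3.50, SE 0.52) from 37.7 to 3.31 CPM, although reads can be shared among these paralogs. The zinc-binding metallothioneins Mt1 (-2.85, SE 0.39) and Mt2 (-2.66, SE 0.36) fell, and 5 of 9 genes of their list fell and none rose (5 and 2 adjusted over the list alone), while 1 rose without knockout 276 or control 279. Of 18 complement genes, 10 fell and 4 rose (11 and 5 adjusted over the list alone), and 2 rose without knockout 275 or control 281. C9 (-2.76, SE 0.15) and C8b (-1.29, SE 0.12) fell, while C6 rose by 1.41 (SE 0.18) and C4b by 0.86 (SE 0.10). Of 13 iron genes, 4 rose and 2 fell (7 and 2 adjusted over the list alone), and 2 rose without knockout 275 or 277 or control 282. Hepcidin (Hamp) was 1.73 (SE 0.48, adjusted p = 0.0496), a call lost without knockout 275 (1.93), 277 (1.63) or 278 (1.35) and without control 279 (1.72), 280 (1.67), 281 (1.98) or 282 (1.59). Tfrc, which erythroid cells also express, fell by 1.51 (SE 0.13). Erythroid markers fell in the same livers.

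The MHC class II median exceeded that of the Kupffer cell list by 0.998 on the log2 scale, but 1 Kupffer cell gene (1.741) lay above it. The class II genes Ifi30 (0.51), Ctss (0.99), H2-DMb2 (1.47), H2-Aa (1.51), H2-Ab1 (1.68) and H2-Eb1 (1.737) lay within the Kupffer cell range. Only Ciita (2.64), Cd74 (2.58), H2-DMa (2.08) and H2-DMb1 (1.885) lay above it. In single libraries the mean log2 CPM of class II genes minus that of Kupffer cell genes was -1.608 to -1.002 in knockouts and -2.50 to -2.04 in controls. Because the class II genes were chosen for their rise, more macrophages, induction of class II genes per cell and more of another antigen-presenting cell type cannot be told apart.

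Y-linked Ddx3y was 124 CPM in knockout 277, 113 CPM in control 279 and 115 CPM in control 281, where Xist was at most 2.35 CPM; in the other 5 libraries Xist was 1082 to 1334 CPM. Gapdh was 13.5 to 26.5 CPM across the 8 libraries, which is low for liver and may reflect reads lost to its pseudogenes. Albumin took 3.32% ± 0.427 of counts in knockout and 6.68% ± 0.773 in control livers (SD, n = 4; exact permutation p = 0.0286, two-sided). The nuclear RNA Malat1 was 7970 ± 257 CPM against 5243 ± 864 CPM (exact permutation p = 0.0286, two-sided).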
